A study of Mus musculus with 59 samples.

How the data were processed

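RNA was sequenced from 59 uterine tissue samples of 29 female mice, and 2 tables of 21706 genes by 59 libraries were used, with gene symbols as identifiers. The first holds estimated counts per gene, which are not whole numbers, made by the authors before the files were deposited; kallisto 0.46.1 and the mouse genome build GRCm39 are named in the submitters' processing notes. The second holds TPM values, deposited by the authors from the same libraries, whose sums per library lay between 685 k and 820 k in these genes. How transcripts were summed to genes, which annotation was used and whether reads or genes were filtered is not given in the sources used here. Per the labels' protocols, a piece of uterus was frozen undigested (U), the rest was digested with dispase, luminal epithelium was scraped out (LE), and a piece of the digested uterus was kept for part of the mice (DU). RNA was isolated as 1 batch per tissue, so tissue and isolation batch cannot be told apart, while genotypes and days share a batch within a tissue. A sequencing batch is not given in the sources used here. The number in a title names the mouse, so that libraries with the same number come from the same animal, and each library of a group is a separate mouse. Every per-sample column was used.

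Estimated counts were rounded to whole numbers. Genes passing filterByExpr (minimum count 10, minimum total count 15) were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on counts scaled by TMM, with the groups as the only terms. The fit held all groups of the tissue or tissues compared, which share 1 estimate of the spread; 15601 genes were tested in LE, 16232 in U, 16194 in DU, 16782 in U with DU and 16665 in LE with U. Biological coefficients of variation were 0.437 in LE, 0.342 in U and 0.259 in DU. P values were adjusted by Benjamini and Hochberg over the genes of a comparison, and genes at an adjusted p under 0.05 were called. Standard errors were taken from the fold change and its F statistic. The comparisons were knockout against control in each tissue and day, D3.5 against D0.5 in each genotype for LE and U, the difference of the knockout effect between days in LE and U, DU against U and LE against U over the mean of 4 genotype and day groups, and the difference of the knockout effect between LE and U on each day. CPM values use the TMM library sizes of the fit within each tissue, and 0.05 CPM was added before taking log2 in scores and on the log axis of a plot. Fold changes between tissues come from a joint fit with its own scaling. They can therefore differ from the ratio of the CPM values given beside them. A fold against a group with no count is a lower bound against 3 counts over that group, and covers counting error only. Where a group held 1 to 3 counts, its level is given with no bound. Estimates near 0 rest on shared reads where a gene has close relatives, as in the Sprr2, Clca, Ly6, Reg3 and globin families, so single members of these are uncertain.

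Of 34 gene lists (423 genes, 420 of them in the tables), written before the data were examined, those with at least 3 tested members entered camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry; camera p values were adjusted over the lists of a comparison. Counts of called members are given over all genes tested and, where different, adjusted over the list alone. Esr1 levels were compared with two-sided exact permutation tests of mean log2 CPM. The genes named in each comparison followed a rule: Esr1, Pgr and Wnt7a; the 6 called genes with the highest and the 6 with the lowest log2 fold change (4 and 4 outside the genotype comparisons) with a mean of at least 10 CPM in the higher group, non-overlapping libraries in the genotype comparisons and no predicted name; and from each list up to 3 called members of smallest adjusted p, or 1 member of highest CPM where none was called. Some of these are left out where a list is given by its counts, a few others are not reported here, and genes chosen otherwise are said to be so. The comparisons, tests, this rule and most of the other settings were fixed before the data were examined.

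Same-mouse libraries were checked for shared deviations from their group means. The median correlation was 0.447 over 13 mice with U and DU (lowest 0.052), 0.341 over 17 mice with LE and U (lowest −0.265) and 0.141 over 13 mice with LE and DU (lowest −0.162). As the pairs come from the same animals, tissue comparisons were refitted with the mouse as a block in the mice with both tissues. These settings were median-of-ratios size factors (the method of DESeq2, computed on the filtered genes) in the same edgeR fit, no filter on low counts, the Wald test of DESeq2 1.42.0, limma voom with sample weights, limma on log2(TPM + 1) over genes with a mean TPM of at least 1, a fit of only the groups compared, each library left out in turn, the block, and stromal and muscle marker scores as a covariate in LE. Others were added after the data were seen: a transcript length covariate (mean log2 CPM of the shortest 25% of expressed genes minus that of the longest, with lengths known for 98.5% of 11694 genes), the same without library 33, LE without mice 35, 36 and 37, the block with the length covariate, and the mice with both tissues without a block. Transcript lengths and gene order came from a reference on another build than the deposited tables, so no coordinates are given.

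The edgeR, limma voom and camera tests in every comparison, the block, and DESeq2 in 2 comparisons were tested on simulated data with 200 changed genes; limma on TPM, the length covariate, the estimated correlation, fry and the permutation test were not. EdgeR recovered 81.8% of 66 genes changed 4-fold and 50.7% of 67 changed 2-fold in LE at D0.5, 63.6% and 22.4% in LE at D3.5, 75.8% and 40.3% in U at D0.5, 86.4% and 28.4% in U at D3.5, 72.7% and 40.3% in DU at D0.5 and 87.9% and 47.8% in DU at D3.5, with 3 to 5 unchanged genes called. For the digestion comparison it recovered 93.9% and 65.7%. The simulated libraries were drawn independently, with no shared mouse and no transcript length trend. These shares therefore do not tell how many digestion changes the real libraries could show. Total counts ranged from 11.3 to 108 M per library (median 19.5). Of the genes, 1123 had a total count of 0 after rounding.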

Results

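Gene expression was measured by RNA sequencing in uterine tissue of 29 mated female mice. Control females carried a floxed and a null allele of Esr1, which encodes oestrogen receptor alpha. Knockout females (epiERα-/-) also carried the Wnt7aCre transgene, which acts in uterine epithelium, so that Esr1 was to be deleted in epithelial cells and kept in stroma and muscle. Females mated with wild-type males were taken at D0.5, the day of the plug, when oestrogen action is high, and at D3.5, when progesterone action is high and the uterus approaches receptivity. The 59 libraries came from 3 kinds of tissue. LE was luminal epithelium scraped out after dispase digestion (26 libraries), U was an undigested piece of whole uterus (20 libraries), and DU was a piece of the dispase-digested uterus (13 libraries), taken to measure what the digestion does to expression. LE held 9 control and 7 knockout libraries at D0.5, and 4 control and 6 knockout libraries at D3.5. U held 6 control and 4 knockout libraries at D0.5, and 5 of each genotype at D3.5. DU held 4 control and 3 knockout libraries at D0.5, and 3 of each genotype at D3.5. Total counts per library, in megacounts (M), ran from 13.5 to 80.3 M in LE (median 19.3), from 11.3 to 108 M in U (median 20.6) and from 14.1 to 46.2 M in DU (median 19.5). No 2 libraries of a group were alike within counting noise, with a lowest chi-square per degree of freedom of 9.76 over 134 pairs.

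Esr1, the deleted gene, was examined first in every library, as CPM (counts per M, scaled by the TMM library size). In LE at D0.5 the 7 knockout libraries held 47.3 ± 12.5 CPM (SD) and the 9 control libraries 192 ± 57.6 CPM, 24.7% of the control level, with no overlap between 34.8 to 62.9 and 110 to 273 CPM (two-sided exact permutation p = 8.74e-05). In LE at D3.5 Esr1 was at 59.7 ± 9.72 CPM in 6 knockout and 127 ± 25.8 CPM in 4 control libraries, 46.9% of the control level, again with no overlap (52.1 to 73.2 against 104 to 162 CPM, exact permutation p = 0.00476). On the authors' TPM the LE groups at D3.5 overlapped, at 13.1 to 20.1 against 15.9 to 44.5 TPM (log2 difference −0.66, exact permutation p = 0.0238). In whole uterus at D0.5 it was at 121 ± 7.17 CPM (n = 4) against 194 ± 62.8 CPM (n = 6, exact permutation p = 0.0238; p = 0.171 on the authors' TPM), and in DU at D0.5 at 145 ± 5.53 CPM (n = 3) against 229 ± 39.3 CPM (n = 4, exact permutation p = 0.0286). In DU at D3.5 the means were 162 ± 21.4 and 215 ± 11.9 CPM with 3 libraries each, where an exact test cannot go below p = 0.1, the value it gave. In whole uterus at D3.5 the means were 152 ± 35.2 and 173 ± 23.6 CPM (n = 5 each, exact permutation p = 0.254). The library labelled knockout 33 held 212 CPM of Esr1, above all 5 control libraries (135 to 195 CPM), while the other 4 knockout libraries held 148, 149, 130 and 123 CPM. Esr1 thus went against the label of that library, the only one from its mouse, and directions drawn from whole uterus at D3.5 include it.

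**Figure D1:**
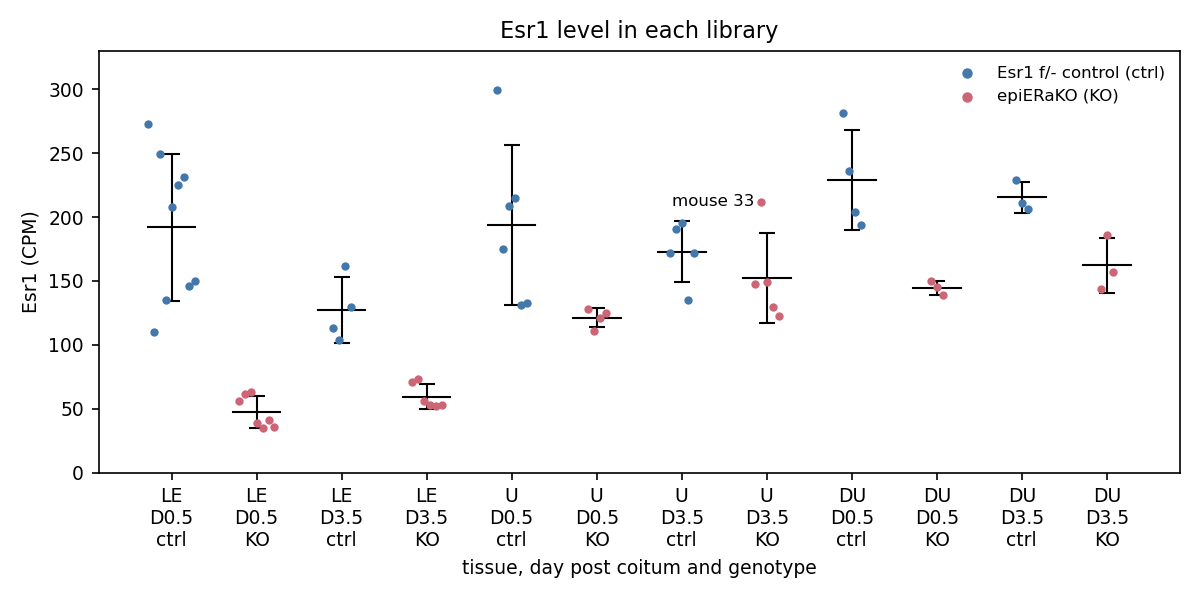
Esr1 counts per M (y axis) in each of the 59 libraries, by tissue, day and genotype (x axis). Points are libraries and bars the group mean ± SD; in LE every knockout library lies below every control library of the same day, and in whole uterus at D3.5 the library labelled knockout 33 lies above all 5 control libraries at 212 CPM.

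Around Wnt7a, the gene whose Cre transgene marks the knockout, 4 genes chosen after their values were seen stood higher in knockout libraries. Chchd4, Tmem43, Xpc and Lsm3 are the 4 genes next to Wnt7a on one side in the gene order of assembly GRCm38.p6. All 4 were higher in LE at D0.5 and in DU on both days, 3 were higher in LE at D3.5 and in U at D0.5, and none passed in U at D3.5 with edgeR, where 682 genes had an unadjusted p under 0.05. Their mean fold change was 1.93 in LE at D0.5, 1.76 in LE at D3.5, 2.13 and 1.87 in U, and 2.34 and 2.35 in DU. Of the 13 other tested genes within 10 places of Wnt7a, 3 were higher and 1 lower in LE at D0.5, 3 were lower in LE at D3.5 and 1 was lower in DU at D0.5. The mean log2 CPM of the 4 genes was 5.77 to 6.2 in the other 8 knockout U libraries, 4.6 to 5.23 in the 11 control U libraries and 4.71 in library 33. Wnt7a itself, an epithelial Wnt ligand, did not pass in any of the 6 genotype comparisons, with a log2 fold change of −0.97 ± 0.40 (SE, adjusted p = 0.0817) in LE at D0.5.

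**Figure D2:**
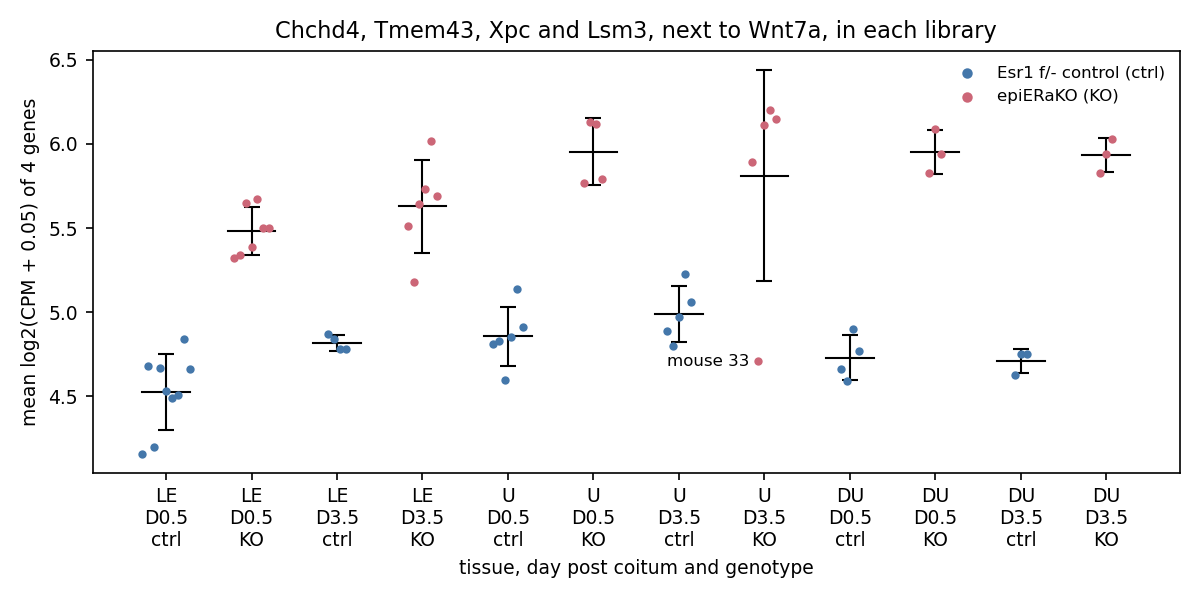
Mean log2 CPM of Chchd4, Tmem43, Xpc and Lsm3 (y axis), 4 genes next to Wnt7a chosen after their values were seen, in each library by tissue, day and genotype (x axis). Points are libraries and bars the group mean ± SD; in LE the knockout libraries lie at 5.18 to 6.02 and the control libraries at 4.16 to 4.87, and the library labelled knockout 33 lies among the control U libraries at 4.71.

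The comparison of knockout and control luminal epithelium at D0.5 asked what epithelial oestrogen receptor alpha contributes when oestrogen action is high. All 16 measured genes of cholesterol synthesis fell. Fdps, which encodes an enzyme of that pathway, stood at 37.2 ± 24.8 CPM (SD, n = 7) in knockout and 216 ± 108 CPM (n = 9) in control LE, a log2 fold change of −2.54 ± 0.41 (SE, adjusted p = 4.11e-05), and Nsdhl at 9.19 against 42.9 CPM. Control library 1 stood apart, with a mean log2 CPM of 4.78 for this list against 6.46 to 7.75 in the other controls and 4.09 to 6.02 in knockout. Of 19 oestrogen-responsive epithelial genes 10 fell and none rose, among them Sprr2a2, a small proline-rich protein gene (20.1 ± 9.69 against 807 ± 382 CPM, log2 fold change −5.33 ± 0.67), and Padi2, a peptidylarginine deiminase gene (19.2 against 385 CPM). Of 10 neutrophil markers 9 rose and Ly6g fell: Retnlg went from 0.736 to 56 ± 33.3 CPM (log2 fold change 6.24 ± 0.62, adjusted p = 6.51e-08) and Mmp8, neutrophil collagenase, from 0.322 to 19 CPM. Single values of the Ly6, Clca and Sprr2 families, which have close relatives, are uncertain. Of 14 unfolded protein response genes 9 rose and none fell (11 when adjusted over the list alone), with Creld2 at 218 against 75.3 CPM, Sdf2l1 at 128 against 46.4 CPM and the chaperone gene Hyou1 at 832 against 341 CPM.

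Epithelial structure genes were also lower in knockout LE at D0.5. Of 15 general epithelial markers 7 fell and none rose (10 when adjusted over the list alone), with the keratin genes Krt19 at 570 against 1860 CPM and Krt8 at 784 against 2070 CPM, and the adhesion gene Epcam at 807 against 1680 CPM. Of 18 cell junction genes 11 fell and 2 rose, with the gap junction gene Gja1 at 52.6 against 265 CPM and Cldn23 at 14.2 against 78.9 CPM. Of 14 interferon-stimulated genes 3 fell (4 when adjusted over the list alone): Bst2, Irf7 and Oasl2 had log2 fold changes of −1.20, −1.21 and −0.85. The mean log2 CPM of this list was 8.50 in knockout library 21, above every control (6.35 to 7.76), and 5.76 to 6.78 in the other knockouts, which control library 1 (6.35) lay among. These 7 lists passed camera: cholesterol synthesis (adjusted p = 5.15e-12), neutrophil (1.53e-06), unfolded protein response (1.53e-06), oestrogen-responsive (0.000396), general epithelial (0.00221), cell junction (0.00339) and interferon-stimulated genes (0.0453). None passed with an estimated correlation, at an adjusted p = 0.266 for the first 4 of these and 0.291, 0.291 and 0.765 for the others. Stromal fibroblast markers had a median log2 fold change of 0.07 with no gene of 11 called, and the stromal gene Dcn stood at 749 against 539 CPM (adjusted p = 0.481).

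Other lists held called genes without passing camera. Of 13 progesterone-responsive genes 6 rose and the transcription factor gene Gata2 fell (camera adjusted p = 0.0647). Acod1, the itaconate-forming enzyme gene, went from 86.5 ± 63.3 to 686 ± 307 CPM (log2 fold change 2.99 ± 0.36). A neutrophil source of this rise was not tested in any tissue. Among water and ion transport genes the sodium channel subunit gene Scnn1g rose from 0.976 to 46 CPM, and the chloride channel gene Cftr fell from 148 to 31.4 CPM (7 of 16 rose and 2 fell). Of 8 gland markers 3 rose, among them Foxa2, a transcription factor of glandular epithelium (57.6 against 4.55 CPM), while Prom1 fell (1240 against 4050 CPM). Of 19 chemokine and inflammatory cytokine genes 7 rose and 2 fell, including Cxcl2, a neutrophil chemoattractant (791 against 132 CPM), and Ccl20 (208 against 11.6 CPM), which rose, and Cxcl17 (234 against 696 CPM), which fell. Mmp9, which neutrophils also make, rose from 6.75 to 164 CPM, and the complement gene C3 fell from 29100 to 11100 CPM. Of 8 macrophage markers 5 rose and Cd68 fell, with C1qa at 9.22 against 3.15 CPM. The stratified epithelium list had a median of 0.64, a mean of −0.58 and a camera direction upward, with 1 gene up and 2 down; its mean log2 CPM was 3.06 in control library 9 and −1.75 to −0.09 in the other controls.

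Across all 15601 tested genes, edgeR called 3676 in LE at D0.5, 1708 higher and 1968 lower in knockout. Of these, 1935 changed by at least 2-fold. With DESeq2 size factors 1908 were higher and 1729 lower, on TPM 1515 and 1242, and without knockout library 25 1678 and 1607, so which direction held more genes depended on the scaling and on that library. The highest with non-overlapping libraries were Reg3g, an antimicrobial lectin gene (44.9 ± 29.6 against 0.0753 CPM, log2 fold change 9.17 ± 1.10), Postn (236 against 1.39 CPM), Prok2, Cdh16 (108 ± 53.2 against 1.03 CPM, adjusted p = 1.61e-10), the anion transporter gene Slco1a5 (203 against 2.28 CPM) and the muscarinic receptor gene Chrm3. The lowest were Cuzd1, with no count in any of 7 knockout libraries and 95.6 ± 48.2 CPM in control (at least 5240-fold lower, against 3 counts over the group), Alpl, alkaline phosphatase (1.03 ± 0.431 against 1090 ± 402 CPM, log2 fold change −10.03 ± 0.64, adjusted p = 3.41e-11), Prss32, the imprinted gene Peg10 (6.68 against 2170 CPM), Add2 and Atp2c2. Pgr, the progesterone receptor gene, stood at 13.9 and 14.1 CPM (adjusted p = 0.97).

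**Figure D3:**
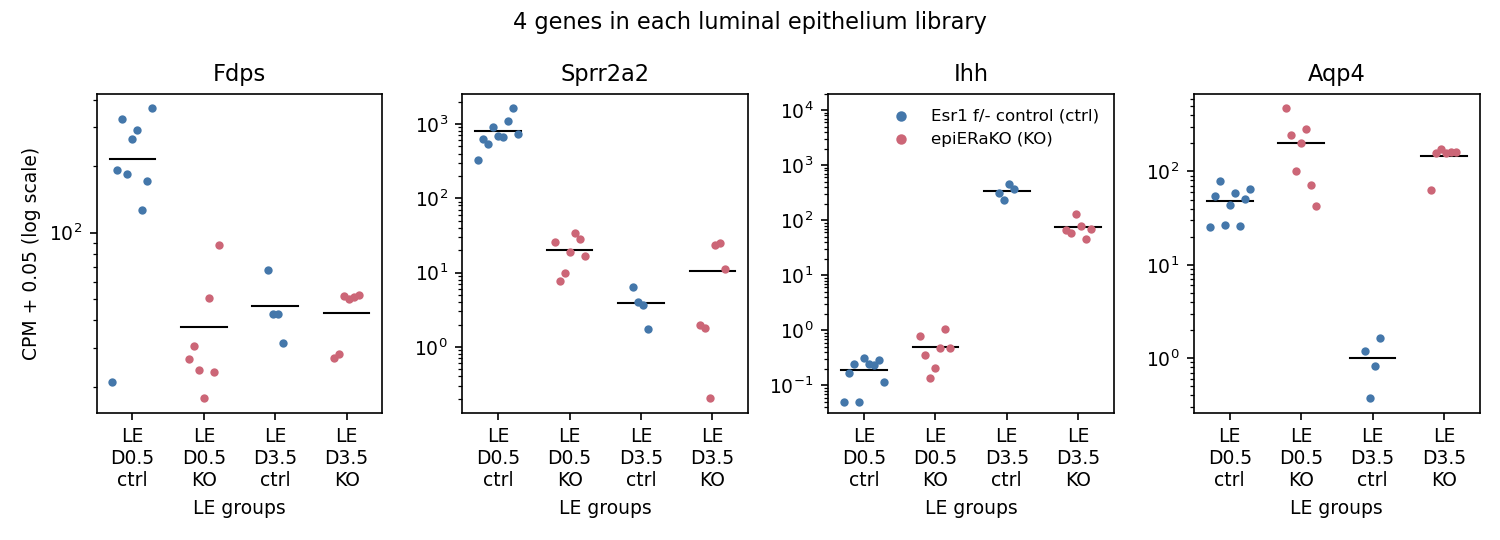
CPM of Fdps, Sprr2a2, Ihh and Aqp4 (y axis, log scale, 0.05 CPM added) in each luminal epithelium library by day and genotype (x axis). Points are libraries and bars group means; Fdps averaged 37.2 CPM in knockout and 216 CPM in control at D0.5, and Ihh 74.6 and 344 CPM at D3.5.

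In luminal epithelium at D3.5 the same comparison addressed the progesterone-dominated state before implantation. Of 13 progesterone-responsive genes 4 fell and none rose (5 when adjusted over the list alone). Ihh, the hedgehog ligand through which epithelium signals to stroma, stood at 74.6 ± 29.8 CPM (SD, n = 6) in knockout and 344 ± 90.8 CPM (n = 4) in control, a log2 fold change of −2.20 ± 0.39 (SE, adjusted p = 0.000299). Areg, an EGF receptor ligand gene, stood at 16.9 against 88.3 CPM, and Cyp26a1, which encodes a retinoic acid hydroxylase, at 11 against 144 CPM. Of 19 oestrogen-responsive genes 7 rose and none fell (8 rose and 1 fell when adjusted over the list alone), including Clca1 (340 ± 377 against 5.69 CPM), the mucin gene Muc4 (94.9 against 16 CPM) and the lactoferrin gene Ltf (1950 ± 2340 against 64.5 ± 35.9 CPM). The mean log2 CPM of this list was 5.47, 5.51 and 4.49 in knockout libraries 35, 36 and 37, which stood apart, and 2.92, 2.91 and 2.43 in 31, 32 and 34, against 2.58 to 2.99 in control. Water and ion transport genes rose in 7 of 16 cases with none lower (9 when adjusted over the list alone), led by the aquaporin gene Aqp4 (146 ± 41.1 against 0.958 ± 0.539 CPM, log2 fold change 7.29 ± 0.70, adjusted p = 9.8e-08), Scnn1g and Scnn1b.

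Cell cycle genes rose in 9 of 24 cases and fell in none (19 rose when adjusted over the list alone), with the proliferation marker Mki67 at 111 ± 99.3 against 8.66 ± 3.53 CPM and Aurkb and Ccnb2 at 12.3 against 0.902 and 24.3 against 2 CPM. Their mean log2 CPM was 5.27, 5.86 and 4.69 in knockout libraries 35, 36 and 37 and 3.13, 3.22 and 2.50 in 31, 32 and 34, against 1.90 to 3.23 in control. Of 20 immediate early genes 7 fell and 1 rose: Ier3 stood at 13.8 against 72 CPM and the cytokine signalling inhibitor gene Socs3 at 23.4 against 101 CPM. The mean of that list was 7.39 and 6.97 in control libraries 11 and 15 and 5.59 and 5.55 in 14 and 16, which lay within the 4.88 to 6.09 of the knockout libraries. Of 15 mucosal defence genes 6 rose, among them Pigr, the immunoglobulin transport receptor gene (407 against 133 CPM), with a list mean of 4.59 to 5.59 in libraries 35, 36 and 37, 3.52 to 3.83 in 31, 32 and 34 and 3.00 to 3.49 in control. Interferon-stimulated genes rose in 2 of 14 cases (Ifi44 and Oasl2), with a list mean of 6.09 and 6.53 in libraries 32 and 34, 4.32 to 5.34 in the other 4 and 4.36 to 4.67 in control. Among implantation genes Msx2 rose (36 against 3.06 CPM) and Stat3 fell (236 ± 70.9 against 489 ± 110 CPM), and Foxa2 rose among gland markers (51.2 ± 26.9 against 1.42 CPM). Lgr5, a Wnt-pathway receptor gene, fell (6.53 against 102 CPM), as did the prostaglandin receptor gene Ptger4 (22.7 against 110 CPM). Of 16 cholesterol synthesis genes only Dhcr7 was called, lower at 32.6 against 124 CPM.

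Other cell types also differed in LE at D3.5: stromal fibroblast markers had a median log2 fold change of −0.88 with Hsd11b2 lower, and the erythroid marker Hbb-bs stood at 103 ± 77.3 against 438 ± 461 CPM (adjusted p = 0.0614), with an erythroid mean of 1.17 to 3.20 in libraries 35, 36 and 37, 3.93 to 4.56 in 31, 32 and 34 and 4.51 to 6.41 in control. Camera called 9 lists, namely cell cycle (adjusted p = 0.00117), immediate early (0.00288), water and ion transport (0.00593), progesterone-responsive (0.0129), stromal (0.014), oestrogen-responsive (0.0171), erythroid (0.0175), interferon-stimulated (0.0264) and mucosal defence genes (0.0425). Water and ion transport alone held with an estimated correlation (adjusted p = 0.0394); the progesterone list had an adjusted p = 0.0697, the interferon list 0.817 and the other 6 lists 0.69 with an estimated correlation. In all, edgeR called 2105 of 15601 genes, 1215 higher and 890 lower. On the authors' TPM, limma called 3546 higher and 387 lower, with the median of all genes moved by 0.38, while limma voom called 688 higher and 834 lower. The highest genes were Serpinb7 (19 CPM against 0 in every control library, at least 505-fold), Slco1a5 (at least 330-fold), Moxd1, Aqp4, Prom2 and Lgi2. The lowest were Coch, an extracellular matrix protein gene (0.66 ± 0.395 against 890 ± 546 CPM, log2 fold change −10.40 ± 0.70, adjusted p = 2.37e-10), Abcb5 (0.783 against 110 CPM), Slc26a6 (1.44 against 102 CPM), Lrrtm2, Pcdh17 and Syn2. Pgr was at 138 and 153 CPM (adjusted p = 0.834). Without mice 35, 36 and 37, left out after the data were seen, 1131 genes were called.

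Tested as a difference between the days, the knockout effect in luminal epithelium changed for several gene groups. Of 19 oestrogen-responsive genes 13 had a higher log2 fold change at D3.5 than at D0.5 and none a lower one, with differences of 7.06 for Clca1, 6.74 for Sprr2a2 and 2.99 for Muc4 (camera adjusted p = 2.12e-06). Cholesterol synthesis genes differed the same way in 13 of 16 cases (15 when adjusted over the list alone), with 4.42 ± 0.89 (SE) for Sqle and 2.79 for Nsdhl (8.29e-08). Progesterone-responsive genes differed the other way, 5 lower and 1 higher of 13, with −4.00 ± 0.65 for Ihh and −3.58 ± 0.56 for Acod1 (camera adjusted p = 0.000312), as did unfolded protein response genes, 8 of 14 lower (8.87e-07), with −1.86 for Creld2. Camera also passed interferon-stimulated (0.000689), cell cycle (0.00351), general epithelial (0.0177) and cell junction genes (0.0193) upward, and neutrophil (0.00563), erythroid (0.0102) and stromal markers (0.0177) downward. The progesterone list alone held with an estimated correlation (adjusted p = 0.0191), the others lying between 0.352 for the oestrogen-responsive and 0.608 for the cell cycle genes. Among the largest single differences were 13.62 for Peg10 and 9.64 for Muc21 upward and −7.89 for Fpr1, −7.23 for Orm1, −6.90 for Nr4a3 and −6.80 for Lgr5 downward. The Esr1 difference was 0.93 ± 0.30 (adjusted p = 0.0318). EdgeR called 2575 genes, 1485 higher and 1090 lower, and limma on TPM 2704 higher and 685 lower; without mice 35, 36 and 37, whose libraries stood apart at D3.5 in the oestrogen-responsive (4.49 to 5.51, mean log2 CPM, against 2.43 to 2.92 in the other knockouts) and cell cycle lists, edgeR called 1814.

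In whole uterus at D0.5 cholesterol synthesis, oestrogen-responsive and interferon-stimulated genes were lower in knockout. Of 16 cholesterol synthesis genes 13 fell and none rose (16 when adjusted over the list alone), with Cyp51 at 27.5 ± 7.23 CPM (SD, n = 4) against 116 ± 65.8 CPM (n = 6), a log2 fold change of −2.08 ± 0.42 (SE), and Idi1 at 12.9 against 69.8 CPM. Control library 1 lay with the knockouts in this list (4.08, other controls 5.57 to 6.61, knockout 3.85 to 4.71). Of 14 interferon-stimulated genes 7 fell (11 when adjusted over the list alone), among them Zbp1, Oas1a and Bst2 (184 against 428 CPM); the list mean was 7.57 in knockout library 21, within the 6.90 to 8.09 of control, and 5.61 to 6.34 in the other knockouts. Of 19 oestrogen-responsive genes 7 fell (10 when adjusted over the list alone), with Sprr2a2 at 10.4 against 373 CPM, Sprr2f at 206 against 2050 CPM and C3 at 3690 against 12300 CPM. Neutrophil markers rose in 6 of 11 cases (8 when adjusted over the list alone), with the granule protein gene Ngp higher by 4.52 on the log2 scale and Mmp8 at 43.7 ± 25.1 against 2.46 CPM. Of 9 macrophage markers Fcgr1 and Cd68 fell. The macrophage mean was 5.25 in knockout library 21, 6.00 to 6.15 in the other knockouts and 5.99 to 6.79 in control. Chemokine genes rose in 6 of 19 cases and fell in 1: Cxcl2 stood at 378 against 48.4 CPM and Ccl3 at 41.3 against 2.66 CPM, while Ccl28 fell. Their mean was 6.39 and 5.84 in knockout libraries 25 and 27, 4.49 and 3.88 in 21 and 26, 2.70 in control library 1 and 4.28 to 5.14 in the other controls. In the progesterone-responsive list 3 rose: Acod1 (57.9 ± 33 to 470 ± 187 CPM), the histamine-forming enzyme gene Hdc, and Lrp2. A neutrophil source was not tested. Immediate early genes rose in 4 of 20 cases, including Zfp36, Socs3 and Gadd45b, with a list mean of 7.30 and 6.96 in libraries 25 and 27, 6.41 in 26 and 5.71 in 21, below every control (5.91 to 6.72). Herpud1 rose among unfolded protein response genes.

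General epithelial markers fell in 3 of 15 cases in the same libraries (Epcam, Krt8 and Krt19, at log2 fold changes of −1.17, −1.66 and −2.12) and stromal markers rose in 2 of 11 (Pdgfrb at 341 against 208 CPM and Lum), with a stromal mean of 8.63 in library 21, 9.36 to 9.56 in the other knockouts and 8.71 to 9.37 in control. The 14 lists that passed camera were cholesterol synthesis (adjusted p = 2.14e-18), interferon-stimulated (3.55e-12), oestrogen-responsive (6.51e-10), neutrophil (6.69e-09), cell junction (2.91e-06), general epithelial (1.81e-05), unfolded protein response (0.000205), macrophage (0.00063), progesterone-responsive (0.00242), chemokine (0.00526), stromal (0.00871), immediate early (0.0133), lymphocyte (0.0217, downward) and Hedgehog genes (0.032), the last with Gli1 higher. None held with an estimated correlation; the lowest adjusted p was 0.0695 for the oestrogen-responsive list, followed by 0.0767 for cholesterol synthesis, neutrophil and cell junction genes and 0.103 for interferon-stimulated genes. EdgeR called 809 of 16232 genes, 328 higher and 481 lower, but 361 in a fit of only these groups and 1949 with the length covariate, while DESeq2 called 1268 and limma voom 2251. The highest were Cdh16 (49.9 ± 32.9 against 1.11 CPM, log2 fold change 5.49 ± 0.66), Slco1a5, Gkn3, Scnn1g, Mmp8 and Ccl3. The lowest were Cuzd1 (−9.08 ± 0.59), Alpl (1.38 against 399 ± 185 CPM, −8.10 ± 0.60, adjusted p = 9.81e-08), Prss32, the diamine oxidase gene Aoc1 (0.55 against 101 CPM), Muc21 and Atp2c2. The Esr1 log2 fold change was −0.68 ± 0.21 with an adjusted p = 0.0635 over all genes. Without knockout library 25, which had the deepest sequencing of the group, 459 genes were called.

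Whole uterus at D3.5 showed few gene differences between genotypes. Only 3 genes were called, all higher in libraries labelled knockout, among them Clca1 (8.59 ± 10.1 against 0.507 ± 0.261 CPM, SD, n = 5 each, log2 fold change 4.08 ± 0.68, SE, adjusted p = 0.0487) and the basal keratin gene Krt15, chosen after its values were seen (63.7 ± 89.4 against 0.0174 CPM, adjusted p = 0.0289), at 216 CPM in library 35, 70.9 in 37, 23.2 in 32, 8.53 in 34 and 0 in 33. Erythroid markers were lower as a list, with no member called over all genes and 5 of 5 lower when adjusted over the list alone; Hbb-bs stood at 76.9 ± 37 against 246 ± 102 CPM (adjusted p = 0.166). That list passed camera (adjusted p = 1.04e-20) and held with an estimated correlation (adjusted p = 0.00544). Gland markers (camera adjusted p = 0.000212, 0.0521 with an estimated correlation) were lower in 3 of 9 cases when adjusted over the list alone, with a list mean of 3.30 in library 33, within the 3.04 to 4.41 of control, and 1.56 to 1.99 in the other knockouts. Stratified epithelium genes (3.15e-05, 0.0521 with an estimated correlation) were higher in 3 of 6, where Krt5 stood at 13.2 against 0.0498 CPM (adjusted p = 0.0848) and the list mean was −0.46 in library 35, −2.56 to −1.07 in the other knockouts and −2.96 to −2.57 in control. Immediate early (6.02e-06), unfolded protein response (1.93e-05) and endothelial genes (0.00296) also passed downward, and water and ion transport (0.0149), general epithelial (0.0241) and mucosal defence genes (0.0376) upward, with an adjusted p of 0.434, 0.434, 0.163, 0.0521, 0.599 and 0.597 with an estimated correlation. The general epithelial mean was 4.51 in library 33, below every control (4.65 to 5.61), and 5.51 to 5.83 in the other knockouts. The gp130 receptor gene Il6st (log2 fold change −0.59) and the growth factor gene Igf1 (−0.05) were not called. EdgeR called 3 of 16232 genes against 682 at an unadjusted p under 0.05; DESeq2 called 79 and limma voom 1446. Without the library labelled knockout 33 the count was 112, 42 higher and 70 lower, and it was 0 without any one of the 5 control libraries 11, 12, 13, 14 and 16 or the knockout libraries 35 and 37, and 1 without 32.

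The knockout effect in whole uterus differed between the days for 232 genes, 153 with a higher and 79 with a lower log2 fold change at D3.5, a comparison that includes the library labelled knockout 33. Cholesterol synthesis genes were higher in 1 of 16 cases (13 when adjusted over the list alone), and oestrogen-responsive genes in 4 of 19 (10 when adjusted over the list alone), with 5.70 for Sprr2a2 and 5.51 for Clca1. Interferon-stimulated genes had none called and 11 of 14 higher when adjusted over the list alone. Neutrophil markers differed downward in 2 of 11 cases, Mmp8 by −5.70 and Ngp by −6.45, and progesterone-responsive genes in 2 of 13, Acod1 by −3.21 and Hdc by −1.98. Immediate early genes differed downward in 4 of 20, with −2.80 for Egr1 and −2.50 for Socs3. Of the 19 lists that passed camera, cholesterol synthesis (adjusted p = 9.15e-15), interferon-stimulated (1.19e-13) and oestrogen-responsive genes (1.7e-09) led upward, and unfolded protein response (6.66e-09), neutrophil (1.45e-08) and erythroid genes (2.2e-07) downward. None held with an estimated correlation, where the lowest adjusted p was 0.0637 for the oestrogen-responsive list. Alpl (8.06 ± 0.69, SE, adjusted p = 1.58e-06), Peg10 (7.46), Arg1 (7.11) and Prap1 (5.78) were the highest single genes. Spink1 was the lowest, with no count in control U at D0.5 and so no finite difference, and 9.85 CPM in knockout at D0.5 (67.8 against 39.5 CPM at D3.5). Lgr5 differed by −4.40, Ccl3 by −4.23 and Fpr1, a receptor gene of phagocytes, by −4.12. DESeq2 called 510, limma voom 1022 and edgeR with the length covariate 647. Leaving out one D0.5 knockout library gave 137 genes without 25, 139 without 27 and 370 without 21.

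Digested uterus at D0.5, a mixed tissue that still held epithelial markers, showed many of the D0.5 changes. Of 14 interferon-stimulated genes 10 fell (12 when adjusted over the list alone), with Irf7 at 89.1 against 243 CPM; control library 1 had a list mean of 6.67, within the 5.65 to 6.70 of knockout (other controls 7.52 to 7.85). Oestrogen-responsive genes fell in 6 of 19 cases (9 when adjusted over the list alone; Sprr2a2 at 9.6 against 274 CPM) and cholesterol synthesis genes in 2 of 16 (11 when adjusted over the list alone; Sc5d at 30.5 against 48.8 CPM, log2 fold change −0.67 ± 0.17, SE), with control library 1 at a list mean of 4.08 (other controls 5.59 to 6.10, knockout 3.77 to 4.83). Neutrophil markers rose in 6 of 11 cases, with S100a8, a neutrophil calcium-binding protein gene, at 483 against 46.3 CPM. Chemokine genes rose in 8 of 19 and fell in 2, with Cxcl2 at 344 against 32.9 CPM and Ccl3 and Ccl4 higher by 3.86 and 3.22 on the log2 scale. The chemokine mean was 6.47 and 5.73 in knockout libraries 25 and 27 and 4.21 in 26, within the 3.35 to 4.75 of control. Unfolded protein response genes rose in 6 of 14 (Herpud1 at 204 against 98.1 CPM), and Acod1 rose from 36.7 to 389 CPM among 4 progesterone-responsive genes that rose. Stromal markers rose in 4 of 11 cases (Lum at 660 against 371 CPM, Pdgfra and Pdgfrb) and smooth muscle markers in 3 of 9 (Acta2 at 3160 against 1740 CPM), beside a fall of 2 of 15 general epithelial markers. Lists passing camera numbered 13, led by interferon-stimulated (adjusted p = 5.51e-10), oestrogen-responsive (1.4e-07), unfolded protein response (6.76e-07), cholesterol synthesis (5.45e-06), neutrophil (5.59e-06) and stromal genes (5.63e-06). With an estimated correlation these had an adjusted p = 0.302, except cholesterol synthesis at 0.489, and none of the 13 held. EdgeR called 1306 of 16194 genes, 630 higher and 676 lower, and limma on TPM 302 higher and 909 lower; DESeq2 called 2147, and a fit of only these groups 411. Cdh16, Wfdc21, Slco1a5, Gkn3 (45.3 against 1.93 CPM), Mmp8 and Mylk2 were highest, and Muc21 (0 in 3 knockout libraries, at least 457-fold lower), Prss32 (at least 342-fold lower), Atp2c2, Alpl (−7.31 ± 0.38), Cuzd1 and Peg10 lowest. Esr1 was lower (−0.66 ± 0.14, adjusted p = 0.0123). Without control library 9 more were higher (691) than lower (648). The count was 608 without control library 5, 642 without knockout library 25 and 720 without 27.

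In digested uterus at D3.5 gland markers were lower as a list, with 2 implantation genes lower and 1 transport gene higher. Gland markers fell in 2 of 8 cases and rose in none (4 fell when adjusted over the list alone): Sox9, a transcription factor gene, stood at 3.48 against 23.6 CPM (log2 fold change −2.75 ± 0.34, SE) and Wfdc3 at 0.0755 against 12.3 CPM (−7.22 ± 0.89). The gland list passed camera (adjusted p = 5e-08) and held with an estimated correlation (adjusted p = 0.019). Of 17 implantation genes Il6st fell, at 491 ± 68 against 1090 ± 19.2 CPM (SD, n = 3 each, log2 fold change −1.15 ± 0.15, adjusted p = 0.00392), as did Stat3 at 187 against 321 CPM. That list had a median of 0.05 and a mean of −0.27 and passed camera downward (adjusted p = 0.0205, 0.258 with an estimated correlation); its median was −0.13 on the authors' TPM. The endothelial gene Vwf fell (85.9 against 191 CPM; list camera adjusted p = 0.000288, 0.383 with an estimated correlation). Aqp4 rose (14.1 ± 8.32 against 0.425 CPM, adjusted p = 0.00663), with its list at a camera adjusted p = 0.0115 (0.372 with an estimated correlation). The gap junction gene Gjb2, Lamb3, Ces1d, Lratd1 and Krt15 also rose (Krt15 at 84.5 ± 117 against 0 CPM, at least 2210-fold, with 219 CPM in library 35, 29 in 32 and 5.54 in 34). Krt83, Tmem213, Tmprss11g, the transporter gene Abcb5 (0.287 against 11.3 CPM) and Serpina3n (3.14 against 118 CPM) were also among the lowest. Stratified epithelium (0.00171), eosinophil (0.00316) and general epithelial genes (0.0205) passed camera upward, at an adjusted p of 0.314, 0.289 and 0.932 with an estimated correlation. The stratified list mean was −0.38 in library 35, from a mouse that stood apart in LE, −1.97 and −1.74 in 32 and 34 and −2.90 to −2.67 in control. EdgeR called 93 genes, 19 higher and 74 lower, and 202 in a fit of only these groups, while DESeq2 called 253 and limma voom 337. Leaving out one library gave 47 without control 14, 45 without control 16, 34, 46 and 40 without knockout 32, 34 and 35.

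**Figure D4:**
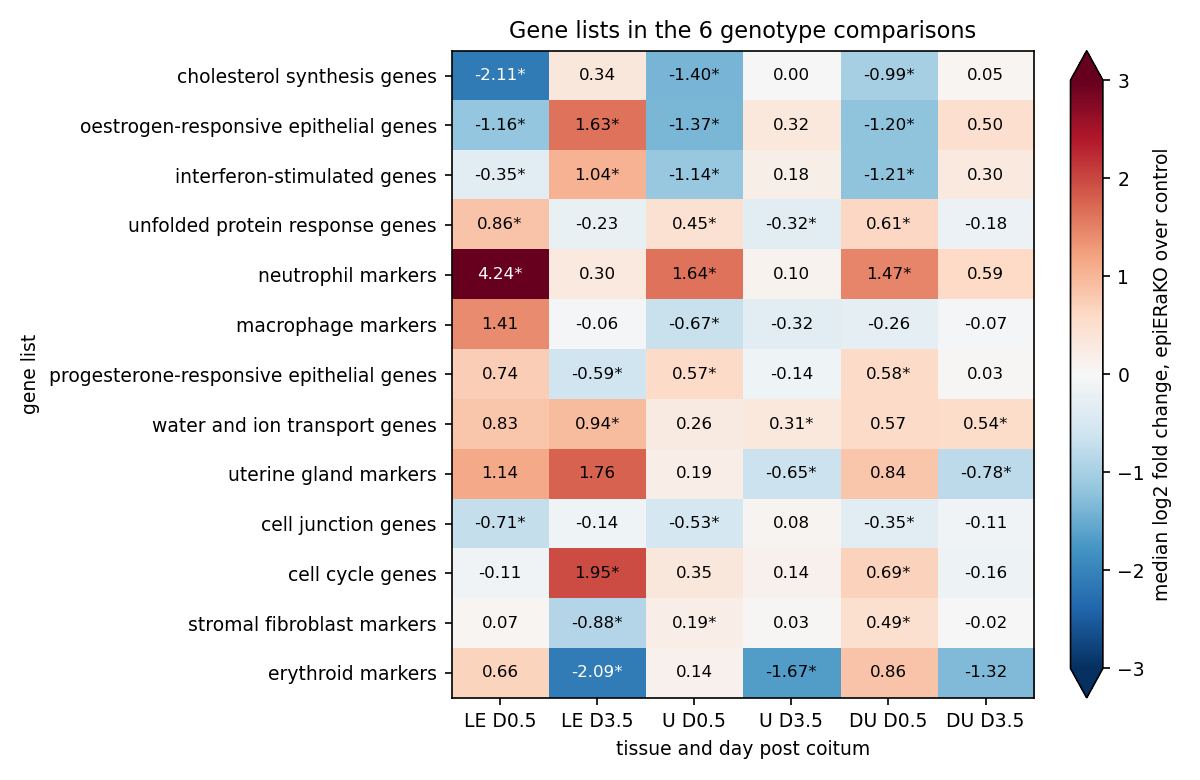
Median log2 fold change, knockout over control, of 13 gene lists (y axis) in the 6 genotype comparisons (x axis), as colour from −3 to 3. Stars mark lists with a camera adjusted p under 0.05; cholesterol synthesis genes have medians of −2.11, −1.40 and −0.99 in LE, U and DU at D0.5, and neutrophil markers medians of 4.24, 1.64 and 1.47.

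At D0.5 the calls in different tissues overlapped; these libraries come in part from the same mice, so the number by independent lists is not what no shared response would give. Of the genes called in LE and U, 230 were higher in both (34.9 by independent lists) and 395 lower in both (60.8 by independent lists), with r = 0.63 across genes, which are not independent replicates. U and DU shared 214 higher (12.8) and 334 lower (20.2) genes, r = 0.76 across genes. In LE, D0.5 and D3.5 shared 287 higher (133) and 211 lower (112) genes, while 104 (97.4) and 193 (153) went opposite ways, r = 0.13 across genes.

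Between D0.5 and D3.5 control luminal epithelium moved from oestrogen-responsive to progesterone-responsive expression. Of 13 progesterone-responsive genes 12 rose, among them the endocytic receptor gene Lrp2 (4850 ± 2390 CPM at D3.5, n = 4, against 18.6 CPM at D0.5, n = 9, SD), and Ihh rose from 0.138 to 344 ± 90.8 CPM (log2 fold change 11.36 ± 0.49, SE, adjusted p = 3.45e-15). Pgr rose from 14.1 to 153 CPM (3.44 ± 0.30). Of 19 oestrogen-responsive genes 16 fell and 1 rose, with Muc4 going from 6290 to 16 CPM. All 14 interferon-stimulated genes fell, as did 15 of 16 cholesterol synthesis genes and 15 of 19 chemokine genes, each with 1 higher, 11 of 14 unfolded protein response genes, and 9 of 15 mucosal defence genes with 1 higher (Pigr by −5.31 on the log2 scale). The cytokine gene Lif fell from 355 to 2.11 CPM, the anion exchanger gene Slc26a4 from 429 ± 220 CPM to no count in 4 libraries (at least 11400-fold), and Ptgs2, the inducible prostaglandin synthase gene, by −5.68. Erythroid markers rose in 5 of 5 cases, Hbb-bs by 4.28. Of the 11 lists that passed camera, the progesterone list (adjusted p = 6.41e-13) held with an estimated correlation (adjusted p = 3.98e-05); the oestrogen-responsive (4.48e-08), cholesterol (1.45e-06) and interferon lists (1.19e-05) had an adjusted p = 0.168, 0.351 and 0.351 with it. EdgeR called 6861 genes, 3303 higher and 3558 lower, and limma on TPM 2903 higher and 2763 lower.

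In knockout luminal epithelium 10 of 13 progesterone-responsive genes rose from D0.5 to D3.5, while Acod1, chosen after its value was seen, fell (log2 fold change −1.16). Ihh rose from 0.446 to 74.6 CPM (log2 fold change 7.36), Sox17 by 3.29, Gata2 by 2.91 and Pgr by 3.31. Cell cycle genes rose in 21 of 24 cases, with Rrm2 higher by 3.97; at D3.5 the mean log2 CPM of this list was 4.69 to 5.86 in libraries 35, 36 and 37 and 2.50 to 3.22 in 31, 32 and 34, against 1.26 to 3.76 at D0.5, and 5375 genes were called without those 3 mice. Of 10 neutrophil markers all fell, S100a8 from 480 ± 235 to 0.384 CPM (−10.37 ± 1.20), and 16 of 19 chemokine genes fell, Cxcl2 from 791 to 0.55 CPM. Unfolded protein response genes fell in 14 of 14 cases (Creld2 from 218 to 31.8 CPM), mucosal defence genes in 10 of 15 (the complement gene Cfb from 18500 to 421 CPM) and oestrogen-responsive genes in 12 of 19 with 1 higher. Cholesterol synthesis genes fell in 6 of 16 and rose in 1 (camera adjusted p = 0.143). Wnt7a rose (2.46, adjusted p = 7.34e-05). Of 10 lists passing camera, the unfolded protein response (adjusted p = 8.5e-18), progesterone (8.74e-08) and mucosal defence lists (8.74e-08) held with an estimated correlation (adjusted p = 0.0169, 0.00202 and 0.0268), while the neutrophil list (8.43e-07) had 0.0993 and the cell cycle list (0.000145) 0.639. EdgeR called 6488 genes, 3333 higher and 3155 lower, and limma on TPM 5799 higher and 1657 lower. More were lower with DESeq2 size factors (3238 and 3326), without library 25 (3029 and 3140), without library 36 (3066 and 3167) and without mice 35, 36 and 37 (2379 and 2996). The control and knockout lists shared 1870 higher (706 by independent lists) and 2065 lower (720) genes.

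In control whole uterus, a mixed tissue, Hedgehog genes changed from D0.5 to D3.5. Of 9 Hedgehog genes 8 rose, with Gli1, a target of the pathway, going from 15.3 ± 8.51 CPM (SD, n = 6) to 235 ± 11.4 CPM (n = 5), and Igf1 rose from 55.2 ± 14.2 to 703 ± 79.9 CPM (log2 fold change 3.67 ± 0.19, SE). Progesterone-responsive genes rose in 11 of 13 cases (Ihh from 1.35 to 54.3 CPM), cell cycle genes in 23 of 24 and endothelial markers in 7 of 8. Oestrogen-responsive genes fell in 15 of 19 and rose in 1, with Clca1 going from 4520 ± 2500 to 0.507 CPM (−13.12 ± 0.89), and interferon-stimulated genes fell in 14 of 14. Mucosal defence (13 of 15), general epithelial (13 of 15), cell junction (13 of 18) and chemokine genes (15 of 19) fell with none higher. Of 18 lists passing camera, 10 held with an estimated correlation, among them oestrogen-responsive (adjusted p = 0.00185), progesterone-responsive, Hedgehog and mucosal defence genes (0.00696 each). Pgr rose (1.48 ± 0.31, adjusted p = 0.000812). EdgeR called 5549 genes, 2632 higher and 2917 lower, limma on TPM 3010 higher and 1967 lower. Limma voom called 3914 higher and 3848 lower, and edgeR with the length covariate 4051 and 3910. In the knockout, with the library labelled knockout 33 among 5, Hedgehog genes rose in 7 of 9 cases (Gli1 from 35.1 to 243 CPM), Igf1 by 3.59 and progesterone-responsive genes in 8 of 13 with 2 lower. Chemokine genes fell in 16 of 19 (Cxcl2 from 378 ± 193 to 0.0451 CPM), neutrophil markers in 9 of 11 (Csf3r from 402 to 10.2 CPM) and cholesterol synthesis genes in 3 of 16 with 2 higher. There 6 of 16 lists held with an estimated correlation, the oestrogen-responsive and mucosal defence lists at an adjusted p = 0.00556. EdgeR called 4139 genes, 1772 higher and 2367 lower, and limma on TPM 2141 higher and 1535 lower, and edgeR with the length covariate 6455; 1381 higher (287 by independent lists) and 1872 lower (425) genes were shared with control.

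Digested and undigested pieces were compared to measure the effect of dispase digestion. CPM was scaled within each tissue, fold changes in the joint fit, so ratios can differ. No gene was called by edgeR among 16782, with 4055 at an unadjusted p under 0.05 and a lowest adjusted p of 0.139; DESeq2 called 147, limma voom 3502 and limma on TPM 6. With the mouse as a block, over the 13 mice that gave both pieces, edgeR called 7082 genes, 62 with a transcript length covariate added, and 3366 in those mice without the block. The length score, mean log2 CPM of short minus long transcripts, lay between −0.70 and −0.19 in the 13 DU libraries and between −0.77 and 0.59 in the 20 U libraries, and was lower in DU in 11 of the 13 mice with both. Erythroid markers were lower in 4 of 6 cases when adjusted over the list alone, with Hbb-bs at 49.3 against 107 CPM (log2 fold change −1.02 ± 0.28, SE, adjusted p = 0.139), and this list passed camera (adjusted p = 0.000856, 3e-07 with the block, 0.919 with an estimated correlation). Unfolded protein response (0.0185) and general epithelial genes (0.046) also passed downward, each at an adjusted p = 0.919 with an estimated correlation. With the block the first of these lost its call (adjusted p = 0.0678), mucosal defence genes gained one (0.044) and general epithelial genes stood at 2.08e-05; the median of the unfolded protein response list was −0.17, and 0.03 on TPM. Immediate early genes, which dissociation of tissue is known to induce, had 5 of 20 higher when adjusted over the list alone (camera adjusted p = 0.11, 0.936 with the block). With the block and the length covariate, added after the data were seen, they passed upward (1.99e-18) and cell junction genes downward (0.0222), and mucosal defence genes did not pass (0.0589). Fn1 (0.57) and Myh11 (0.36), stromal and muscle genes, had an adjusted p = 0.139. Esr1 stood at 188 and 160 CPM (0.19 ± 0.10, adjusted p = 0.224). Without U control library 8 at D0.5 the count was 2.

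Luminal epithelium differed from whole uterus as epithelium from a mixed tissue. CPM was again scaled within each tissue, so ratios can differ from the joint fit. All 15 general epithelial markers were higher in LE, including Esrp1, an epithelial splicing regulator gene (226 against 67.4 CPM, log2 fold change 2.26 ± 0.09, SE), Elf3 and Cdh1. All 9 smooth muscle markers (Acta2 at 15.2 against 2430 CPM), 11 stromal markers (Pdgfra at 6.25 against 478 CPM) and 8 endothelial markers were lower, as were 8 of 9 macrophage, 10 of 13 lymphocyte and 4 of 4 eosinophil markers. Immediate early genes were higher in 14 of 20 cases, with Fos at 414 against 51.9 CPM, in tissue that had been digested. Cell junction genes were higher in 15 of 18, mucosal defence genes in 12 of 15 and oestrogen-responsive genes in 14 of 19, and Hedgehog genes lower in 7 of 9. The mesothelial markers Msln and Upk3b were higher (2.77 and 2.36). Wnt7a was higher (96 against 17.6 CPM, 2.53 ± 0.28) and Esr1 lower (106 against 160 CPM, −0.47 ± 0.11). Of 16 lists passing camera, general epithelial (adjusted p = 1.52e-17), cell junction (4.76e-11), smooth muscle (2.35e-10) and water and ion transport genes (0.0137) held with an estimated correlation (adjusted p = 0.00336, 0.00696, 0.0424 and 0.0424), and stromal markers (1.8e-08) had 0.152. With the mouse as a block over 17 mice, progesterone-responsive (0.0376), implantation (0.00991) and interferon-stimulated lists (0.0221) also passed. EdgeR called 10965 of 16665 genes, 5174 higher and 5791 lower, and limma on TPM 2896 higher and 6307 lower. With the length covariate and without library 33 more were higher (6014) than lower (5885). Krt13, Krt5, Krt15 and Fat2 were highest and Hmcn2 (0.0157 against 125 CPM), Npas4, Nmur2 and Chodl lowest.

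The knockout effect at D0.5 was compared between luminal epithelium and whole uterus. The fall of Esr1 was larger in LE by −1.31 ± 0.29 (log2 difference ± SE, adjusted p = 0.00778). Macrophage markers differed upward in LE in 3 of 9 cases, Adgre1 by 2.32 and C1qa by 2.28 (camera adjusted p = 1.24e-05), with U knockout library 21 at a list mean of 5.25 (other U knockouts 6.00 to 6.15), and among neutrophil markers Retnlg differed by 5.70 (0.00087). The immediate early genes Egr1 and Zfp36 differed by −1.97 and −1.49 (5.13e-05). Mucosal defence (0.0114), unfolded protein response (0.0225) and lymphocyte genes (0.0356) passed upward and cholesterol synthesis genes (0.0113) downward, and none of the 7 held with an estimated correlation, with a lowest adjusted p = 0.436. With the mouse as a block the lymphocyte (0.53) and immediate early lists (0.178) lost their call, and steroid receptor (0.00632), gland (0.00036), stromal (0.0399), interferon-stimulated (0.000127) and water and ion transport lists (0.018) gained one. With the length covariate added, immediate early (0.0306) and general epithelial genes (0.034) passed, and stromal and cholesterol synthesis genes (0.0571 each) did not. EdgeR called 271 genes, 186 higher and 85 lower, with Postn (7.20), Reg3g (5.83), Add2 (−5.76) and Coch (−5.28) at the ends, and 480 without LE control library 2. DESeq2 called 480 and limma voom 1355, and the mice with both tissues gave 134 without the block and 262 with it.

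At D3.5 the same comparison, with the library labelled knockout 33 in it, gave 644 genes, 401 higher and 243 lower, against 746 higher and 104 lower by limma on TPM and 726 higher and 809 lower by limma voom. Gland markers differed upward in 3 of 9 cases, Wfdc3 by 5.23, Foxa2 by 4.57 and Cxcl15 by 3.47 (camera adjusted p = 0.000251, 0.0473 with an estimated correlation). Cell cycle genes had none called and 9 of 24 higher when adjusted over the list alone (3.53e-06, 0.892 with an estimated correlation), with a mean in LE of 4.69 to 5.86 in libraries 35, 36 and 37, 2.50 to 3.22 in 31, 32 and 34 and 1.90 to 3.23 in control. Stromal (0.00298) and progesterone-responsive lists (0.038) passed downward, at an adjusted p = 0.892 and 0.191 with an estimated correlation. Moxd1 (7.60), Lgi2 (7.53) and the aquaporin gene Aqp5 (5.62) were among the highest genes, and Coch (−8.50 ± 0.78, SE), Slc26a6 (−5.77) and Abcb5 (−5.40) among the lowest. Esr1 differed by −0.89 ± 0.32 (adjusted p = 0.111). DESeq2 called 1021, limma voom 1535 and edgeR with the length covariate 1026. With the mouse as a block 385 genes were called, against 184 in those mice without it, the progesterone list lost its call (0.0638), and oestrogen-responsive (0.0337) and interferon-stimulated genes (0.00105) gained one. The oestrogen-responsive mean in LE was 4.49 to 5.51 in libraries 35, 36 and 37, 2.43 to 2.92 in the other knockouts and 2.58 to 2.99 in control.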

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

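The tests of library 33, of the genes next to Wnt7a and of the neutrophil markers were chosen after these results were seen, as were the length covariate and the fits without single named libraries; the splits of the samples were planned. In groups of 4 to 9 libraries, 11 measures gave 99 group tests, and in 8 of them a library lay far from the rest of its group; chance flags about 1 in 20 groups. Total counts stood apart in LE D3.5 knockout 36 (14.2 M against 17.7 to 19.4 in the others), U D0.5 control 9 (53.1 against 11.3 to 23.5) and U D0.5 knockout 25 (108 against 16.2 to 22.1). The mean log2 CPM of neutrophil markers was −0.72 in LE D3.5 knockout 36 (others −2.26 to −1.80), and that of macrophage markers 5.25 in U D0.5 knockout 21 (others 6.00 to 6.15). The mean of preimplantation embryo genes was 0.85 in LE D3.5 control 11 (others −3.73 to −3.49) and −2.08 in LE D0.5 knockout 21 (others −3.51 to −2.94).

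The library labelled knockout 33 of whole uterus at D3.5 also stood apart in the genes next to Wnt7a, with a mean log2 CPM of 4.71 for Chchd4, Tmem43, Xpc and Lsm3 against 5.89 to 6.20 in the other 4 libraries of its group. The transcript length trend is argued against, as the score adjusted for it lay −13.1 SDs from the mean of the other 8 knockout U libraries. A deletion that failed in a mouse carrying the transgene cannot be told apart: the score lay by −1.06 from the lowest of those 8 (5.77), which counts against a carrier only if the transgene itself raises these genes, and that stays a hypothesis. A wrong genotype label also stays open: 4.71 lies within the 4.6 to 5.23 of the 11 control libraries, Esr1 was at 212 CPM in this library, and its gland marker mean was 3.30 (D3.5 controls 3.04 to 4.41, other knockouts 1.56 to 1.99). The mouse gave no other library, no biological explanation was tested, and leaving the library out gave 112 called genes in whole uterus at D3.5 in place of 3.

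The same 4 genes had higher means in knockout in all 3 tissues, with 3 of 4 passing in U at D0.5 and none at D3.5. Had they answered to the loss of the receptor in epithelium, their change would be diluted in tissue with less epithelium, as for other genes of like fold in LE, and 1 of 10000 random sets of 4 such genes had a mean log2 fold change as high as theirs in DU at D0.5 (1.23). The length trend left them at 1.10 in U at D0.5. Extra copies carried with the Wnt7aCre transgene are a candidate explanation, as the mean of 1.09 in U lay above the 95th percentile (0.63) of those sets; the 4 genes were picked for their high values, so the comparison with random sets is not independent of that choice, a response of stroma was not tested, and as the construct was not examined this stays a hypothesis.

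Neutrophil markers had a median log2 fold change of 4.24 in LE, 1.64 in U and 1.47 in DU at D0.5. Carry-over of stroma and muscle is argued against by a median of 4.28 in LE with those markers as a covariate. An equal rise of all leukocytes is argued against by macrophage medians of 1.41 in LE, −0.67 in U and −0.26 in DU. In LE the macrophage median SE was 0.44 and 5 of 8 markers rose, so a smaller rise of other leukocytes stays open there. Blood is argued against by erythroid medians of 0.66 in LE and 0.14 in U, while in DU the erythroid median of 0.86 and the neutrophil rise cannot be told apart, as the erythroid median SE was 0.61. A higher number of neutrophils, or more of their transcripts per cell, may underlie the pattern, and these data cannot separate the 2. Ly6g, counted among the markers, fell in LE.

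The knockout effect differed between groups in each test of a difference. Genes called numbered 2575 between days in LE and 232 in U, and 271 between LE and U at D0.5 and 644 at D3.5; the Esr1 log2 fold change differed by 0.93 between days in LE and by −1.31 between LE and U at D0.5.

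Other splits of the same libraries were set against each count. No other split drawn called as many genes for LE at D0.5 (3676 genes, 1 of 60 splits as large, namely the real one, highest other split 921), LE at D3.5 (2105, 806), U at D0.5 (809, 458) and DU at D0.5 (1306, 1 of 35 splits as large, highest other 477). The same held for the difference between days in LE (2575, 179) and U (232, 55), and for the day comparisons in LE control (6861, 2351), LE knockout (6488, 53), U control (5549, 3693) and U knockout (4139, 2183). It also held for LE against U (10965, 1 of 40 splits as large, highest other 110) and its differences by genotype at D0.5 (271, 0) and D3.5 (644, 99). These shares of 1.67 to 2.86% are the smallest possible here, unadjusted over comparisons. They make chance unlikely, without excluding it, except for differences of the knockout effect. There, mixing genotypes also removes an effect common to both days or tissues. For LE against U the real split parted libraries of 17 mice, others 9 at the median. For U at D3.5, 3 of 60 splits, the real one included, called as many as 3, and the highest other 11. Chance stays open there, and whether library 33 plays a part was not tested. DU at D3.5 has 10 splits, too few for a share under 0.05, with 93 genes in the real split and 0 in the highest other. For digestion the splits cannot test chance, as no count lies below the real 0 (highest other 707). The real split parted libraries of 13 mice, others 7 at the median. The block gave 7082, or 62 with the length covariate.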

How the results depend on the processing

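Tests added after the data were seen are the length covariate, alone, with the block or without library 33, the fits without mice 35, 36 and 37 and those of the mice with both tissues without a block; the others were planned. Of 139 planned values other than single left-out libraries, 84 stayed within 1.5 times of the count or kept their call and 55 moved; of 276 values with 1 library left out, 253 stayed within 1.5 times. For the values that moved, the cause was not tested. Over 293 pairs of a named gene and a comparison, 2232 of 2385 values under other settings were the same, 125 weaker and 28 stronger, and with 1 library left out 4358 of 4591 were the same, 228 weaker and 5 stronger; none reversed. LE at D0.5 kept its count in every setting tried (3829 with the stromal and muscle covariate). The DESeq2 Wald test called 1268 genes in U at D0.5, 79 in U at D3.5, 2147 in DU at D0.5, 253 in DU at D3.5, 510 for the difference between days in U, 147 for digestion, and 480 and 1021 for the difference between LE and U at D0.5 and D3.5. Limma voom called 2251 in U at D0.5, 1446 in U at D3.5, 337 in DU at D3.5, 1022 for the difference between days in U, 3502 for digestion, and 1355 and 1535 for the difference between LE and U at D0.5 and D3.5. Limma on TPM called 3933 in LE at D3.5, 0 in U at D3.5 and 6 for digestion. TPM moved the median of all genes by 0.38 in LE at D3.5, 0.32 in its difference between days, 0.39 in knockout LE between days, 0.39 in the difference between LE and U at D3.5, −0.22 in LE against U, 0.19 for digestion, 0.14 and 0.12 in U control and knockout between days and −0.11 in DU at D0.5, so changes on that scale are relative to these shifts; DESeq2 size factors moved it by at most 0.05. Of the lists passing camera, TPM turned the sign of the median of 2, implantation genes in DU at D3.5 and unfolded protein response genes in digestion. With DESeq2 size factors 1 gene was called in U at D3.5, and with no filter 5. A fit of only the groups compared called 361 in U at D0.5, 0 in U at D3.5, 411 in DU at D0.5 and 202 in DU at D3.5.

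The length covariate gave 1949 in U at D0.5, 23 in U at D3.5, 647 for the difference between days in U, 6455 for U knockout between days, 1 for digestion and 431 and 1026 for the difference between LE and U at D0.5 and D3.5. Without library 33 and with this covariate there were 154 in U at D3.5, 630 for the difference between days and 1 for digestion. LE at D3.5 without mice 35, 36 and 37 gave 1131. With the block digestion called 7082 genes, 62 with the length covariate and 3366 in the same mice without a block. For the difference between LE and U the block gave 385 at D3.5 and 262 at D0.5. The same mice without it gave 184 and 134. The block moved no other count by over 1.5 times. It changed no list call beyond those beside the tissue comparisons, all at the preset correlation. The digestion test within each genotype and day called 0 genes with edgeR in all 4 groups (831, 491, 517 and 443 at an unadjusted p under 0.05; other tools were not run within groups).

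Lists that passed camera numbered 7 in LE at D0.5 (0 with an estimated correlation, 13 with fry), 9 in LE at D3.5 (1, 3), 14 in U at D0.5 (0, 8), 9 in U at D3.5 (1, 1), 13 in DU at D0.5 (0, 8), 7 in DU at D3.5 (1, 1), 11 between days in LE control (1, 23) and 10 in knockout (3, 17), 18 in U control (10 with an estimated correlation) and 16 in U knockout (6), 11 for the difference between days in LE (1) and 19 in U (0, 11), 3 for digestion (0, 0), 16 for LE against U (4, 29), and 7 and 4 for its difference by genotype at D0.5 (0, 0) and D3.5 (1). The Esr1 difference in U at D0.5 on the authors' TPM was −0.63, no longer past the threshold (exact permutation p = 0.171).

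With 1 library left out, counts ranged from 3235 to 3966 in LE at D0.5, 1651 to 2256 in LE at D3.5, 459 to 967 in U at D0.5, 0 to 112 in U at D3.5, 608 to 1528 in DU at D0.5, 34 to 64 in DU at D3.5, 2275 to 2769 and 137 to 370 for the difference between days in LE and U, 6131 to 7055 and 5997 to 6575 between days in LE control and knockout, 4836 to 5492 and 3563 to 3926 in U control and knockout, 0 to 2 for digestion, 10859 to 11097 for LE against U, and 181 to 480 and 477 to 793 for its difference by genotype at D0.5 and D3.5. The libraries behind moves above 1.5 times are 25 in U at D0.5 (459), control 5 (608), 25 (642) and 27 (720) in DU at D0.5, 21 (370), 25 (137) and 27 (139) in the difference between days in U, LE control 2 (480), U control 8 in digestion (2), and at D3.5 those named in the text for U and DU. Without control library 1 the counts at D0.5 were the highest of these ranges in U (967) and DU (1528), and in LE the count stayed within 1.5 times. Genes with no count, 1123 of them, could not be compared at this depth, and the effect of depth on the other results was not tested.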

Other observations

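The list results below were planned; the values of single libraries were picked after the data were seen, with no test. In luminal epithelium at D0.5 several lists moved in both directions without passing camera. Of 16 prostaglandin pathway genes 4 rose and 2 fell in knockout, with the receptor gene Ptger4 at 15.4 ± 3.87 CPM (SD, n = 7) against 60 ± 26 CPM (n = 9) and the synthase gene Ptges at 78.6 against 18.9 CPM. Of 17 implantation genes 2 rose and 3 fell: Lifr, a receptor subunit gene for Lif, stood at 32 against 103 CPM, Msx1 at 74.5 against 155 CPM and Klf5 at 177 against 269 CPM. Lgr5 rose from 1.65 to 11.7 CPM among 15 Wnt pathway genes, of which Fzd10 (5.42 against 27.2 CPM) and 1 more fell. Of 8 ciliated cell markers Dnah5 and Foxj1 rose (log2 fold changes 3.58 and 3.32, at about 1 CPM). The glucocorticoid receptor gene Nr3c1 rose (68.3 against 39.2 CPM), and of 20 immediate early genes 2 rose, Gadd45b among them (81.4 against 19.8 CPM), and 7 fell, Ier3 among them (374 against 1150 CPM).

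At D3.5 knockout LE had higher Sfrp1 (log2 fold change 2.73), Wnt4 (1.57), the prostaglandin transporter gene Slco2a1 (1.93), Gjb2 (1.87), Cldn8 (2.31), the chemokine gene Ccl28 (4.25) and the gland genes Cxcl15 (3.28) and Spink1 (3.47). The inhibitor gene Timp1 (−2.64 ± 0.38, SE, adjusted p = 2.4e-05) and the chaperone gene Hsp90b1 (−0.81) were lower. LE and DU shared 326 higher (68.2 by independent lists) and 468 lower (84.5) genes at D0.5, r = 0.58 across genes, in tissue of the same mice, for which independent lists are not a no-change value, and 18 higher (1.47) and 30 lower (3.95) at D3.5, r = 0.27 across genes.

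In LE D0.5 control 3 Y-linked genes had a mean log2 CPM of 0.28, and in control 9 stratified epithelium genes one of 3.06. Digestion tested within each genotype and day had a lowest adjusted p of 0.714 in control and 0.993 in knockout at D0.5, and 0.772 and 0.932 at D3.5.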
